A study of Homo sapiens with 12 samples.

How the data were processed

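RNA was measured by sequencing of poly(A)-selected, strand-marked libraries (TruSeq Stranded mRNA kit, per the labels' protocols) from THP1, a human monocytic leukaemia cell line grown in suspension. The 12 libraries fell into 4 groups of 3 by the genotype and treatment labels: control cells in PBS, control cells in LPS, BRD3 knockdown cells in PBS and BRD3 knockdown cells in LPS. Per the labels, LPS was given at 100 ng/ml for 3 h. Knockdown was by a short hairpin RNA, per the series' design text, and the labels gave the control genotype as wild type, with no statement on a control hairpin. Nothing in the labels said that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

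The authors deposited 1 table of gene counts per library. Per the file headers, the counts are whole numbers of read pairs per gene from featureCounts 1.6.4, run in paired-end mode and counting only pairs in the reverse-strand orientation, with no normalization. Multi-mapped reads were not counted, per the file headers, so counts of near-identical copies (CCL3 and CCL3L1, CCL4 and CCL4L2, metallothioneins, canonical histones) are low and uncertain. The aligner was not given in the sources used here. The submitters' processing notes name the build GRCh38, also called hg38. The gene coordinates in the deposited count tables differ from it: of 52526 gene identifiers shared with a GRCh38 annotation (GENCODE), only 322 (0.61%) had the same start and end, and the last gene of chromosome 1 ended at 249231242 in the files against 248937043 there. Coordinates printed here are those of the files, 1-based, and the build they belong to was not stated. The files held 63677 genes, of which 5904 lay on alternate or patch sequences with 0 counts. Gene symbols are those of the files, which use IL8 for CXCL8 and DDX58 for RIG-I.

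Total counts per library ran from 16912692 to 17398291 in control PBS, from 16190419 to 27307305 in control LPS, from 17055841 to 19740291 in knockdown PBS and from 24438780 to 26432481 in knockdown LPS. Mitochondrial genes took between 2.43% and 3.36% of counts. Reads carried no molecular identifiers, so counting error is a lower limit of the technical error.

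Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's default filter on the 4 groups (15156 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries. The 5 contrasts were LPS against PBS in control cells, LPS against PBS in knockdown cells, knockdown against control in PBS, knockdown against control in LPS, and the difference of the LPS responses. P-values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05. Levels (CPM, counts scaled to library size) were computed from the deposited counts with TMM-scaled library sizes, and log2 CPM used a prior count of 2. Fold changes are on the log2 scale of the model with their standard error (SE).

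Libraries of a group were compared before averaging. Replicates 1 and 2 of control PBS, of control LPS and of knockdown LPS differed by 1.16, 1.09 and 1.26 times the variance that sampling alone gives, over genes with at least 20 counts in the pair, while the other 9 same-group pairs differed by 40.2 to 94.6 times. A chi-square test over genes still found a difference in each of the 3 pairs (p = 6.1e-39, 5.2e-15 and 1.2e-95). Means and SDs count each of these pairs as 1 sample, which leaves n = 2, 2, 3 and 2. The test with all 12 libraries was fixed before the data were examined. A fit in which the counts of each pair were summed, with 9 samples, was added after the data were examined, and its count stands beside the main count of each comparison as "with near-identical pairs counted once".

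Replicate numbers were shared between groups. Deviations from the group means correlated between control PBS and control LPS libraries of the same number (r = 0.519, 0.540 and 0.746 across genes). Replicates 1 and 2, which were near-identical, correlated as highly with the other number (0.541 and 0.549), while replicate 3 had at most -0.644 with the other numbers, so that only replicate 3 was told apart from the other 2. Between knockdown PBS and knockdown LPS the correlations of the same number were -0.148, 0.494 and 0.325, and between genotypes all were below 0, so that the numbers were not taken as pairs there. Knockdown PBS replicate 3 and knockdown LPS replicate 3 differed by only 5.39 times the sampling variance, the lowest value after the 3 near-identical pairs, and were kept as separate samples. The next lowest value among all pairs of libraries was 23.4.

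There were 29 gene lists, fixed before the data were examined, and 28 of them had at least 3 tested members. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Genes named in the text were chosen by a rule fixed at the same time: the BET family, 10 inflammatory genes fixed by name, the 6 rising and 6 falling protein-coding genes of largest fold change at 5 CPM or more in the higher group with values that do not overlap, and up to 3 called members of each functional list at 1 CPM or more. Other named genes are said to have been chosen after their values were seen. Not every gene that the rule covers is reported here.

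Alternatives planned before the data were examined were other scalings, other count filters, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, each library left out in turn, and other thresholds. The model was tested on a single simulated data set, drawn from the control PBS means for every group and the real library sizes. Genes were changed in control LPS alone, and the knockdown groups kept the control PBS means. The simulated libraries were drawn independently, so near-identical pairs were not reproduced. For LPS against PBS in control cells, over 14621 genes, it recovered 12% of genes changed 1.5-fold, 62% of genes changed 2-fold, 92% at 4-fold and 94% at 8-fold, with 4 false calls among 134. False calls numbered 7 among 145 for knockdown in LPS and 12 among 117 (10.3%) for the difference of LPS responses, above the 5% aimed at, and 0 for the other 2 comparisons. Recovery was not measured for the other comparisons.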

Results

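The study recorded the transcriptome of THP1 monocytes with and without knockdown of BRD3, a bromodomain protein of the BET family that binds acetylated histones, in PBS and after 3 h of LPS, a bacterial cell wall component sensed through TLR4. Each of the 4 groups had 3 libraries, with 16190419 to 27307305 counted read pairs per library. Replicates 1 and 2 differed by little more than sampling noise in control PBS, control LPS and knockdown LPS, and each such pair was counted as 1 sample in means and SDs. The first principal component of log2 CPM took 53.2% of the variance and parted the genotypes. Control replicate 3 lay between the others on it, at -11.95 in PBS and -30.78 in LPS, against -60.36 to -69.98 for control replicates 1 and 2 and 37.33 to 56.55 for the knockdown libraries. Knockdown PBS replicate 1 stood alone on the second component, at 88.05. A PBS and an LPS library of the knockdown cells were nearly alike: replicate 3 lay at 49.66 and -7.88 in PBS and at 49.82 and -7.92 in LPS, and the libraries differed by 5.39 times the sampling variance, against 23.4 or more for every other pair outside the near-identical ones.

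**Figure D1:**
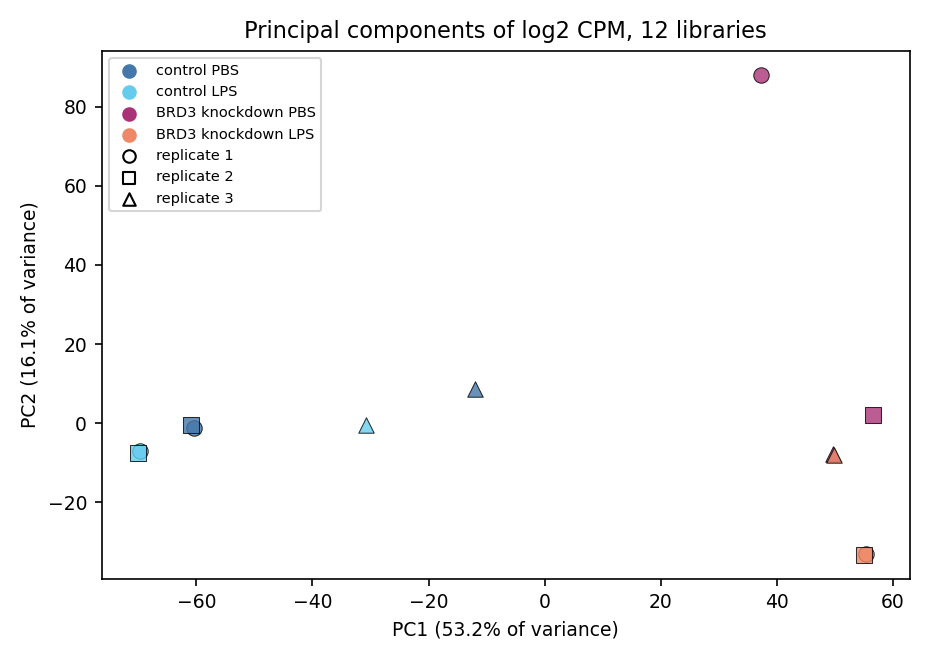
Principal components of log2 CPM over 15156 genes, with PC1 and PC2 scores on the axes, 1 point per library, colour for group and shape for replicate number; near-identical replicates 1 and 2 overlap. PC1 parts control from knockdown libraries, and knockdown PBS replicate 1 lies apart at 88.05 on PC2.

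The target gene was examined first, as a check of the labels. BRD3 transcripts (ENSG00000169925, chromosome 9, 136895427 to 136933657 in the files' coordinates) were not lower in the libraries labelled BRD3 knockdown by more than the spread between libraries. BRD3 stood at 73.1 ± 10.6 CPM in control PBS (SD, n = 2), 56.0 ± 4.67 in control LPS (n = 2), 65.4 ± 24.2 in knockdown PBS (n = 3) and 46.1 ± 8.72 in knockdown LPS (n = 2). Single knockdown PBS libraries held 86.5, 70.6 and 39.0 CPM, against 64.5, 66.7 and 80.6 CPM in control PBS. In LPS the knockdown libraries held 53.1, 51.4 and 39.9 CPM, and the control libraries 60.1, 58.4 and 52.6 CPM. The log2 fold change was -0.11 ± 0.24 (SE) in PBS and -0.25 ± 0.24 in LPS, with edgeR adjusted p = 0.78 and 0.484. With near-identical pairs counted once, the 95% interval ran from -0.85 to 0.53 in PBS and from -1.04 to 0.48 in LPS. The related BRD2 did not pass the test either, with log2 fold changes of -0.08 ± 0.13 in PBS and -0.19 ± 0.13 in LPS. The PBS estimate depended on the libraries: it was 0.11 without knockdown PBS replicate 3, -0.005 without control PBS replicate 3 and -0.37 without knockdown PBS replicate 1. Without the last and with near-identical pairs counted once it was -0.45, with an interval from -1.12 to 0.23. The LPS estimate was -0.13 without knockdown LPS replicate 3, and none of these passed. Because the target does not separate the groups, the groups are named by their labels, and every knockdown contrast below compares libraries labelled BRD3 knockdown with libraries labelled control. Those labels give the control as wild type without stating a control hairpin. An effect of introducing a hairpin is therefore not separated from one of the knockdown in any of these contrasts.

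**Figure D2:**
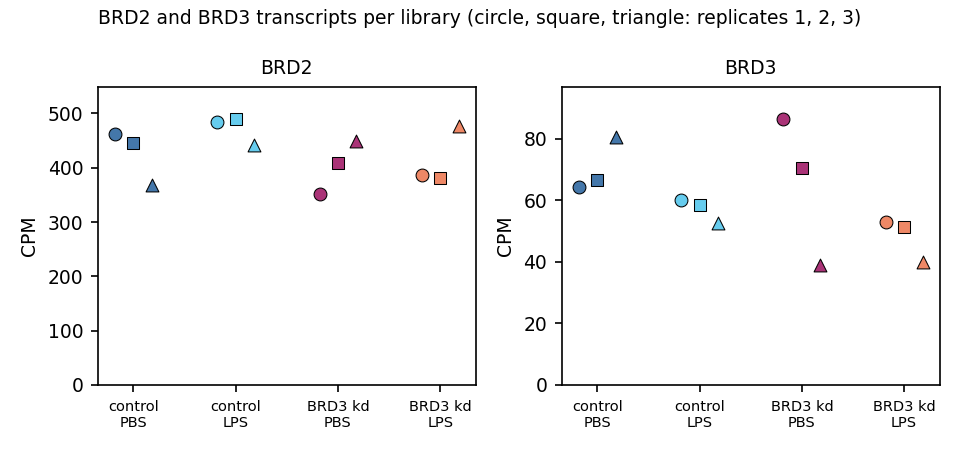
CPM of BRD2 and BRD3 in each library, with the 4 groups on the x axis, linear y axes from 0 and 1 point per library. BRD3 in knockdown PBS ranged from 39.0 to 86.5 CPM, across the range of the control libraries.

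LPS was compared with PBS in control cells to find the genes that respond to it. Of the lists fixed beforehand, 6 of 18 chemokines, 10 of 26 NF-kB members and feedback genes and 10 of 41 interferon-stimulated genes rose. IFIT2 (ENSG00000119922, chromosome 10, 91061712 to 91069033 in the files' coordinates), an interferon-induced antiviral gene, rose 26.5-fold, from 21.7 ± 2.71 to 524 ± 139 CPM (SD, n = 2 and 2; edgeR adjusted p = 0.000268). NFKBIZ (chromosome 3, 101546835 to 101579866), an inducible regulator of NF-kB, rose 10.2-fold, from 12.8 ± 5.12 to 135 ± 33.5 CPM (adjusted p = 0.000195). The chemokine genes CXCL10 and CXCL11 rose 25.6-fold and 26.1-fold, to 1067 ± 925 and 92.8 ± 64.3 CPM (adjusted p = 0.0117 and 0.00129). IRG1, which makes itaconate in macrophages, went from 0.0579 ± 0.00194 to 55.1 ± 44.7 CPM, and the cytokine gene IL6 from 0.0605 ± 0.0855 to 10.9 ± 10.2 CPM (adjusted p = 0.000961 and 0.00273). No fold is given for IRG1, IL6 and IL1A, since their control PBS counts were close to 0. These folds and p-values come from the fit of all 12 libraries, so folds need not equal ratios of the printed means. With near-identical pairs counted once, IFIT2 and NFKBIZ passed (edgeR adjusted p = 0.0296 for both). CXCL10, CXCL11, IRG1 and IL6 did not pass in that fit.

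In total 93 of 15156 genes passed, 87 higher and 6 lower, of which 83 rose by at least 1 on the log2 scale. Of the chemokine list, 6 of 18 tested members rose over all genes, and 16 when adjusted over the list alone. Of the pro-inflammatory cytokines, 3 of 17 rose (14 adjusted over the list alone), among them TNFSF15 at 9.05-fold and IL1A, from 0.0878 ± 0.0443 to 1.77 ± 0.110 CPM. Of the NF-kB members and feedback genes, 10 of 26 rose (22 adjusted over the list alone), with TRAF1 at 9.97-fold and TNIP3 at 10.5-fold, and of the interferon-stimulated genes 10 of 41 rose (17 adjusted over the list alone), with IFIT3 at 10.2-fold and OASL at 6.92-fold. These 4 lists kept their call with an estimated correlation (adjusted p = 0.00236, 0.00277, 0.00236 and 0.0248). Another 7 lists had higher medians by the preset correlation alone, and no member of them passed over all genes. They were immediate early genes, TLR4 signalling, inflammasome, antigen presentation, anti-inflammatory regulators, mitochondrially encoded genes and ribosomal proteins, with adjusted p between 0.184 and 0.58 with an estimated correlation.

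The genes that fell were led by PDK4, a kinase that restrains pyruvate oxidation, from 7.50 ± 2.22 to 0.816 ± 0.254 CPM. CEBPA, a transcription factor of myeloid differentiation, fell from 47.9 ± 9.76 to 20.1 ± 2.33 CPM (log2 fold change -1.22 ± 0.16, adjusted p = 0.00357). Several inflammatory genes had large but unequal changes that did not pass in edgeR. They were TNF (4.75-fold, adjusted p = 0.414), IL1B (7.35-fold, 0.205), IL8 (8.01-fold, 0.197), CCL2 (5.74-fold, 0.303) and PTGS2 (11.6-fold, 0.0517). The PBS level of TNF, IL1B, IL8 and CCL2 differed between control replicates, as in IL1B, at 49.6 ± 58.4 CPM. PTGS2 differed mainly in control LPS, at 62.7, 58.7 and 7.7 CPM, against 4.17, 4.74 and 2.2 in control PBS. All of these 5 genes passed when control libraries alone were fitted with the replicate number as a block, a fit added after the data were examined (adjusted p between 0.000462 and 0.0277, and across all their alternatives between 1.29e-06 and 1). IL10 and NLRP3 had log2 fold changes of 0.39 ± 1.18 and 0.17 ± 0.20 and passed in none of these. The blocked fit of control libraries counted near-identical replicates as separate. With them counted once it had only 2 samples per group.

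The count depended on the libraries. It was 4 with near-identical pairs counted once (IFIT2, TNFAIP2, NFKBIZ and CXCL9), 1776 in control libraries alone with the replicate block (898 higher, 878 lower) and 1245 in that fit with pairs counted once. Both blocked fits called all 93 genes, but they use the same control libraries, so this is no independent support. The first counts near-identical replicates as separate, and the second has only 2 samples per group to estimate the spread. Without control PBS replicates 1 or 2 it was 49 or 47, and without control LPS replicates 1 or 2 it was 61 or 60.

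**Figure D3:**
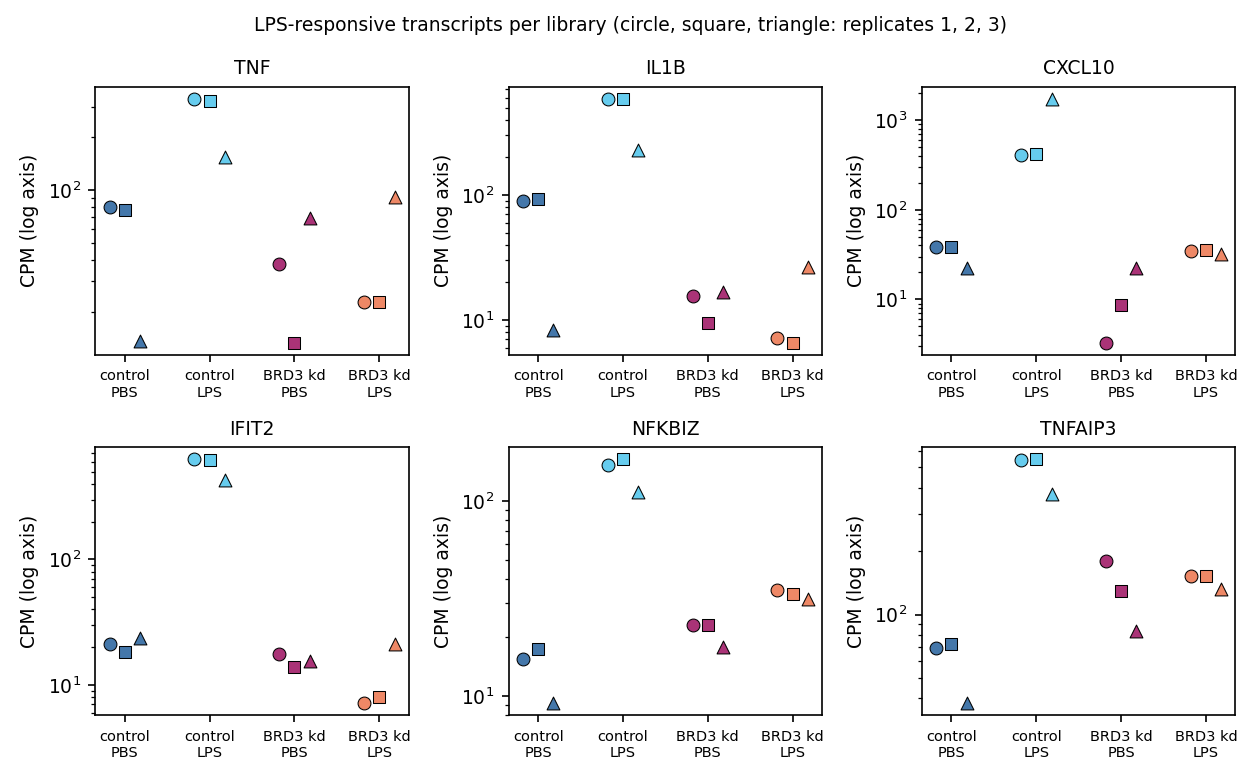
CPM on log axes of 6 LPS-responsive genes, with the 4 groups on the x axis and 1 point per library. In control LPS libraries IFIT2 and NFKBIZ lie above every other library, while in knockdown LPS libraries TNFAIP3 stays between 134 and 153 CPM.

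The same comparison in the libraries labelled BRD3 knockdown asked whether those cells respond to LPS. No gene passed in edgeR (1906 at an unadjusted p under 0.05), against 19 by DESeq2 (1 higher, 18 lower), and with near-identical pairs counted once none passed (236 unadjusted). IFIT2 stood at 15.7 ± 1.74 CPM in PBS (SD, n = 3) and 14.3 ± 9.51 in LPS (n = 2). CXCL10 stood at 11.5 ± 10.1 and 33.4 ± 2.11 CPM, TNF at 39.9 ± 27.8 and 57.2 ± 48.4, IL1B at 13.9 ± 3.88 and 16.6 ± 13.8, and IL8 at 15.7 ± 7.23 and 20.6 ± 16.3. The NF-kB feedback genes NFKBIZ and TNFAIP3 stood at 21.4 ± 3.01 and 131 ± 48.7 CPM in PBS, and 32.8 ± 1.85 and 143 ± 13.6 in LPS. The 83 genes induced in control cells had a median log2 fold change of 0.16 in knockdown cells, with 56 of them positive, against 1.88 in control cells. Of 28 lists, 12 were called with the preset correlation, among them NF-kB members and feedback genes upward (median log2 fold change 0.47) and interferon-stimulated genes downward (median -0.53, 4 of 41 positive), and none of the 12 with an estimated correlation (adjusted p = 0.471 for both named lists). LXR targets and lipid efflux genes had a median of -0.91, MYC targets of 0.44 (28 of 28 positive), ribosomal proteins of 0.19 (36 of 36 positive) and mitochondrially encoded genes of -0.17 (0 of 13 positive), also with adjusted p = 0.471. By replicate number the median LPS change was -0.60, -0.84 and -0.05 for interferon-stimulated genes and 1.26, 0.08 and 0.01 for MYC targets, on the scale of log2(CPM + 1). For NF-kB members and feedback genes it was 0.46, 0.41 and 0.25, with 18, 23 and 25 of 26 higher. The 83 induced genes had 0.08, 0.13 and 0.17, with 48, 50 and 71 higher. Numbers were not taken as pairs in knockdown cells, and LPS replicates 1 and 2 were near-identical, so values by number are not independent. Left-out libraries moved the number of genes that passed for LPS in knockdown cells. It was 535 (259 higher, 276 lower) without knockdown PBS replicate 3 and 18 without knockdown LPS replicate 3. These are the libraries that were nearly alike, and among the 83 induced genes these fits called 0 and 1, none of them higher.

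The difference of the LPS responses between the genotypes was tested directly. It passed for 10 genes, all with a smaller response in the libraries labelled BRD3 knockdown; on simulated data this test made 12 false calls among 117. IFIT2 had a log2 difference of -5.11 ± 0.50 (SE, edgeR adjusted p = 0.00589), IFIT3 of -3.84 ± 0.53 and IFIT5 of -2.86 ± 0.30 (adjusted p = 0.0275 and 0.00717). TNFAIP3, which encodes the A20 inhibitor of NF-kB, had -2.87 ± 0.41, NFKBIZ -2.72 ± 0.32, NCOA7 -2.24 ± 0.30 and TNFAIP2 -1.32 ± 0.20 (adjusted p = 0.0334, 0.0115, 0.0251 and 0.046). The other 3 were DDX58, STAT5A and ZC3HAV1, chosen after their values were seen. The lists of chemokines, interferon-stimulated genes, pro-inflammatory cytokines and NF-kB genes had median log2 differences of -3.16, -1.57, -1.86 and -0.97, and kept their call with an estimated correlation (adjusted p = 0.0239, 0.0239, 0.0445 and 0.0445). With near-identical pairs counted once no gene passed in edgeR (292 at an unadjusted p under 0.05). DESeq2 called 124 genes (13 with a positive difference, 111 negative) and the fit with the replicate block 16, all negative. Of the 54 genes called without knockdown PBS replicate 3, 13 had a positive difference and 41 a negative one. The count was 54 without knockdown PBS replicate 3, 31 without knockdown LPS replicate 3, 20 without knockdown PBS replicate 1, and 2 to 4 without any 1 of replicates 1 and 2 of control PBS, control LPS or knockdown LPS, or without knockdown PBS replicate 2.

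The libraries labelled BRD3 knockdown were compared with control libraries in PBS to see what differs without a stimulus. Of the monocyte and macrophage identity list 19 of 31 tested members fell and none rose (22 fell when adjusted over the list alone and 5 with near-identical pairs counted once, adjusted p = 0.217 for the list with an estimated correlation). The complement genes C1QA and C1QC stood at 32.1 ± 28.6 and 24.3 ± 23.4 CPM in control PBS (SD, n = 2) and at 0.443 ± 0.0988 and 0.103 ± 0.0817 in knockdown PBS (n = 3). Their log2 fold changes were -6.43 ± 0.91 and -8.05 ± 1.10 (SE, edgeR adjusted p = 0.00132 and 0.00113). S100A12, a calgranulin of monocytes, fell from 21.3 ± 15.4 to 0.769 ± 0.632 CPM, and the haemoglobin scavenger receptor CD163 from 23.7 ± 24.4 to 0.526 ± 0.202 CPM. CD14, the LPS co-receptor, fell from 66.8 ± 74.7 to 5.55 ± 5.04 CPM (adjusted p = 0.0226), and the control libraries themselves held 119, 121 and 14 CPM. The granule enzyme gene MPO went from 1.24 ± 0.0703 to 6.41 ± 2.82 CPM (log2 fold change 2.35 ± 0.40, adjusted p = 0.00329), and the survival gene BCL2 from 37.9 ± 18.1 to 124 ± 53.2 CPM (1.88 ± 0.33, adjusted p = 0.00426).

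In total 2545 genes passed, 1332 higher and 1213 lower, and 1426 changed by at least 1 on the log2 scale. Of the immature myeloid and granule genes 7 of 14 rose and 1 fell (8 and 1 adjusted over the list alone, 0 and 0 with pairs counted once, adjusted p = 0.59 with an estimated correlation). KIT went from 1.90 ± 1.88 to 13.1 ± 11.9 CPM and CTSG from 220 ± 133 to 1315 ± 1033 CPM. Knockdown PBS replicate 1 held 2490 CPM of CTSG, against at most 913 in any other library, and without it 3 of the 14 rose and 2 fell. Of the interferon-stimulated genes 19 of 41 fell (25 adjusted over the list alone, 3 with pairs counted once), with GBP1 at 7.02 ± 3.78 against 0.509 ± 0.381 CPM and EPSTI1 at 74.6 ± 9.72 against 13.2 ± 3.56 CPM. That list had adjusted p = 0.59 with an estimated correlation, and 12 of the 41 fell without knockdown PBS replicate 1. Of the anti-inflammatory regulators 6 of 15 fell (7 adjusted over the list alone, 2 with pairs counted once, adjusted p = 0.328 with an estimated correlation), led by IL1RN, the IL-1 receptor antagonist, from 48.8 ± 14.2 to 11.1 ± 6.35 CPM, and IL18BP, from 16.3 ± 1.66 to 4.76 ± 1.88 CPM. Of the metallothioneins and NRF2 targets 8 of 17 fell (9 adjusted over the list alone, 1 with pairs counted once, adjusted p = 0.495 with an estimated correlation), including FTH1, the ferritin heavy chain, from 1491 ± 861 to 817 ± 137 CPM, and MT1M, whose reads may be shared with near-identical copies. Ribosomal proteins were higher in 17 of 36 (26 adjusted over the list alone, 1 with pairs counted once, adjusted p = 0.619 with an estimated correlation). Genes that changed within the ATF4 and unfolded protein response list went both ways, with 5 of 28 higher and 5 lower (0 and 2 with pairs counted once). PDIA4, an endoplasmic reticulum protein disulphide isomerase, fell from 343 ± 47.5 to 104 ± 14.7 CPM (adjusted p = 7.38e-05), and ASNS, asparagine synthetase, went from 17.5 ± 1.72 to 55.4 ± 38.3 CPM (adjusted p = 0.0312). The sterol genes MVK and HMGCS1 rose 2.05-fold and 1.9-fold, and HK1, a hexokinase, fell from 175 ± 30.4 to 92.3 ± 3.88 CPM. CCL2 fell from 53.6 ± 54.7 to 3.99 ± 3.25 CPM (adjusted p = 0.00998), while TNF, IL1B, IL8 and CXCL10 did not pass (adjusted p = 0.67, 0.0755, 0.245 and 0.133).

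With near-identical pairs counted once, 281 genes passed (104 higher, 177 lower), all of them among the 2545, including C1QA, C1QC, S100A12, CD163, GBP1, EPSTI1, IL1RN, IL18BP, MT1M, HK1 and PDIA4; of the 66 called genes named by rule 17 passed, and MPO, KIT, CTSG, BCL2, CD14, CCL2, ASNS, MVK, HMGCS1 and FTH1 did not. Without control PBS replicates 1 or 2 the count was 983 or 1030, with only the groups compared it was 1018, and upper-quartile scaling, which moved the median of all genes to 0.11 on the log2 scale, changed the split to 1693 higher and 993 lower.

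In LPS, libraries labelled BRD3 knockdown were compared with control libraries. The series' title concerns genes regulated by BRD3 in LPS-treated monocytes. BRD3 transcripts were not called lower in the libraries labelled BRD3 knockdown, so the comparison alone cannot say which genes BRD3 regulates. Of the interferon-stimulated genes 39 of 41 fell (40 adjusted over the list alone, 25 with near-identical pairs counted once) and of the chemokines 16 of 18 (17 adjusted over the list alone, 8 with pairs counted once), both with adjusted p = 0.0499 with an estimated correlation. IFIT2 stood at 524 ± 139 CPM in control LPS and 14.3 ± 9.51 in knockdown LPS (SD, n = 2 and 2; log2 fold change -5.53 ± 0.40, edgeR adjusted p = 3.56e-05), and IFIT1 at 374 ± 154 and 9.58 ± 5.65 CPM (-5.35 ± 0.48, adjusted p = 6.87e-05). CXCL10 stood at 1067 ± 925 and 33.4 ± 2.11 CPM, CCL8 at 43.5 ± 26.0 and 0.160 ± 0.0200, and CCL2 at 403 ± 90.9 and 5.44 ± 5.49. SOD2, a mitochondrial superoxide dismutase induced by NF-kB, stood at 1424 ± 501 and 93.3 ± 7.53 CPM (-4.07 ± 0.40, adjusted p = 0.000105). IL1B stood at 407 ± 250 and 16.6 ± 13.8 CPM and TNF at 241 ± 122 and 57.2 ± 48.4 (adjusted p = 0.00208 and 0.0335).

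In total 3498 genes passed, 1660 higher and 1838 lower, and 1941 changed by at least 1 on the log2 scale. Of the anti-inflammatory regulators 11 of 15 fell and 1 rose (the same numbers adjusted over the list alone, 3 and 0 with pairs counted once, and adjusted p = 0.0499 with an estimated correlation), with IL1RN at 103 ± 34.0 against 7.07 ± 0.161 CPM and SOCS1 at 13.6 ± 2.49 against 1.72 ± 1.17. Of the NF-kB members and feedback genes 19 of 26 fell (22 adjusted over the list alone, 6 with pairs counted once, adjusted p = 0.132 with an estimated correlation), with TRAF1 at 104 ± 80.0 against 2.77 ± 0.822 CPM. Of the pro-inflammatory cytokines 10 of 17 fell and 1 rose (10 and 2 adjusted over the list alone, 6 and 0 with pairs counted once, adjusted p = 0.092 with an estimated correlation). IL6 stood at 10.9 ± 10.2 CPM in control LPS and 0.0376 ± 0.00163 in knockdown LPS, where its total was 3 counts. Of the monocyte and macrophage identity genes 21 of 31 fell and 1 rose (23 and 1 adjusted over the list alone, 5 and 0 with pairs counted once, adjusted p = 0.0749 with an estimated correlation). CD14 stood at 36.0 ± 42.7 and 1.19 ± 0.783 CPM, and the control libraries themselves held 66.2, 66 and 5.79 CPM. Of the TLR4 signalling genes 12 of 30 fell (13 adjusted over the list alone, 1 with pairs counted once, adjusted p = 0.0862 with an estimated correlation), among them IRAK2, at 62.8 ± 30.1 against 10.0 ± 8.43 CPM. Of the antigen presentation genes 10 of 20 fell (11 fell and 1 rose adjusted over the list alone, 3 fell with pairs counted once, adjusted p = 0.154 with an estimated correlation), with TAP1 at 396 ± 66.4 against 111 ± 5.35 CPM and HLA-E at 255 ± 8.96 against 127 ± 15.0. Of the immature myeloid and granule genes 5 of 14 rose and 1 fell (7 and 2 adjusted over the list alone, 0 and 0 with pairs counted once, adjusted p = 0.614 with an estimated correlation). Higher genes included MPO (log2 fold change 2.09 ± 0.38), PRTN3, another granule enzyme gene, at 171 ± 88.6 against 489 ± 47.4 CPM, BCL2 (1.79 ± 0.33) and FBLN1, a matrix glycoprotein gene, at 1.13 ± 1.20 against 15.4 ± 3.14 CPM. Ribosomal proteins were higher in 19 of 36 (25 adjusted over the list alone, 1 with pairs counted once), and mitochondrially encoded genes were lower in 5 of 13 (8 adjusted over the list alone, 0 with pairs counted once), both with adjusted p = 0.487 with an estimated correlation.

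With near-identical pairs counted once, 524 genes passed (170 higher, 354 lower), all of them among the 3498; of the 72 called genes named by rule 26 passed, and IL1B, TNF, CD14, SOCS1, IRAK2, MPO, PRTN3, BCL2 and FBLN1 did not. Without control LPS replicates 1 or 2 the count was 1954 or 1949 and without knockdown LPS replicates 1 or 2 it was 2138 or 2150, and the split changed to 2296 higher and 1503 lower with upper-quartile scaling and to 2725 and 1384 with library size alone, which moved the median of all genes to 0.14 and 0.20 on the log2 scale.

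**Figure D4:**
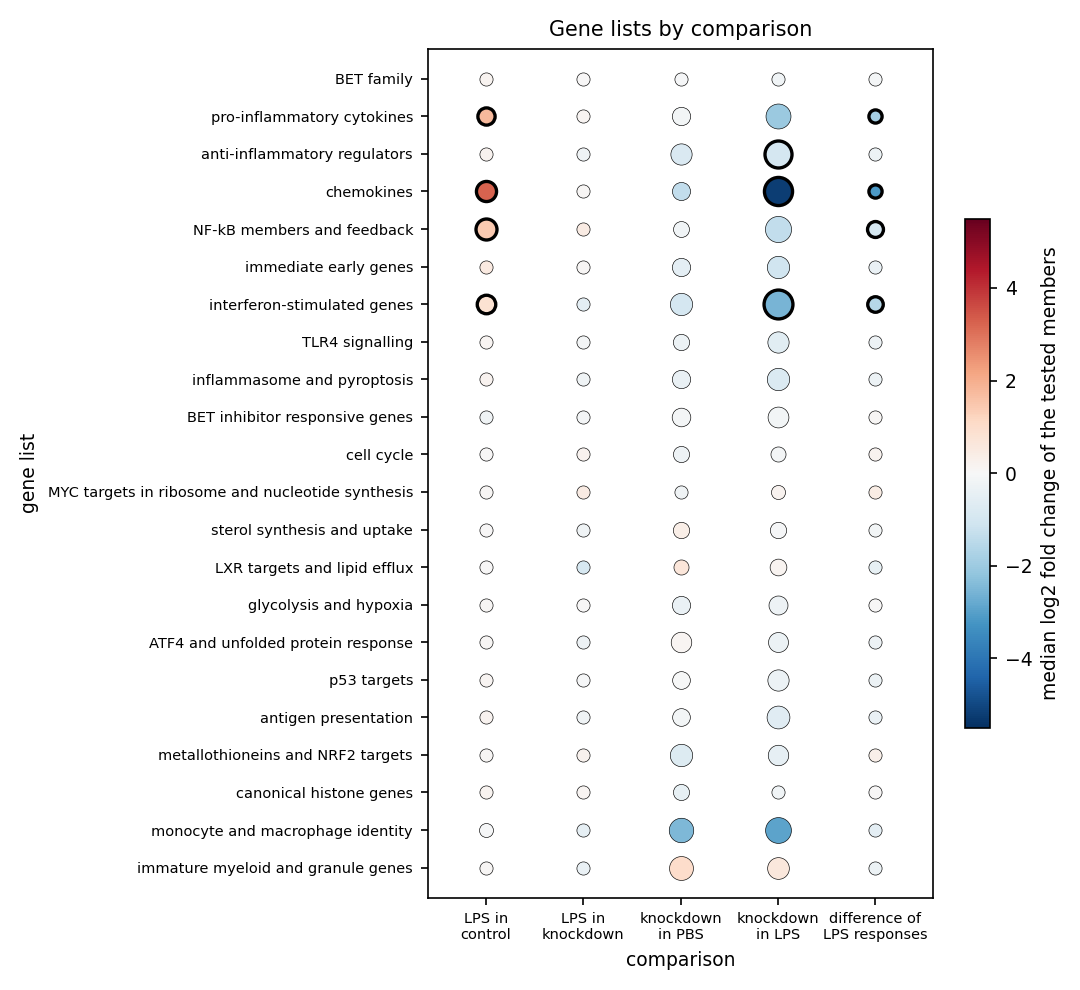
Median log2 fold change (colour) of the tested members of 22 functional gene lists (y axis) in the 5 comparisons (x axis); larger points have a larger share of members past the adjusted p over all genes, and thick outlines mark lists called with both the preset and the estimated correlation. In LPS, chemokines had the lowest median, -5.21, in libraries labelled knockdown.

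The calls of the 2 knockdown comparisons overlapped. The comparisons share no library but are not independent, since control PBS and control LPS replicate 3 deviated together, as did replicates 1 and 2, and knockdown replicate 3 was nearly alike in PBS and LPS, so part of the excess below may come from this. Of the genes called, 858 were higher in both treatments, against 146 for independent lists, and 887 lower in both, against 147, and 6 went in opposite directions. GBP1, IL1RN, CD163, MT1M and PDIA4 were lower in both, and MPO, BCL2 and ZMAT3 higher in both. The log2 fold changes correlated across genes with Pearson r = 0.797 and Spearman rho = 0.713, where genes are not independent replicates. The overlap in the same direction was 199 genes with near-identical pairs counted once. The LPS comparisons in control and knockdown cells could share no called gene in edgeR, since none was called in knockdown cells. Their log2 fold changes had r = 0.106 and rho = 0.129 across genes. By DESeq2 the LPS comparisons shared 1 called gene.

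Of the 83 genes that LPS raised by at least 1 on the log2 scale in control cells, 77 were lower and none higher in LPS in the libraries labelled BRD3 knockdown, with a median log2 fold change of -1.90. In PBS the same genes were 15 lower and 11 higher, with a median of -0.15. Independent lists would share 10.1 genes. Both contrasts use the control LPS libraries, so part of the excess may come from these shared controls. In 20 simulated data sets without a knockdown effect, with a median of 189 induced genes, 0 were called lower. The median log2 fold change of the simulated induced genes was -0.10. The simulated libraries were drawn independently, without near-identical pairs or deviations shared between control PBS and control LPS. They therefore cannot show how much such shared error adds to the excess. The median level of the 83 genes over the control PBS mean was 1.61, 1.61 and 1.86 in the control LPS libraries and 0.03, -0.01 and -0.01 in the knockdown LPS libraries, on the scale of log2(CPM + 1). Of the 83 genes, 55 were lower in LPS and none higher with near-identical pairs counted once. LPS-induced genes could not be defined in knockdown cells, where no gene passed.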

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

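The splits of the libraries and the test of the difference of LPS responses were planned; all other tests given here were chosen only after the result was seen.

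In the fit of all 12 libraries, the LPS response differed between the genotypes for 10 genes by a test of the difference itself. Each of the 10 responded less in the libraries labelled BRD3 knockdown. With near-identical pairs counted once, none of the 10 passed. The log2 difference was -5.106 for IFIT2, -3.842 for IFIT3, -2.859 for IFIT5, -2.867 for TNFAIP3, -2.716 for NFKBIZ and -2.235 for NCOA7. It was -2.102 for DDX58 (RIG-I, a sensor of viral RNA), -1.44 for STAT5A, -1.367 for ZC3HAV1 and -1.322 for TNFAIP2. The same test on gene lists, with the preset correlation, called 16 of 28. Median log2 differences were -3.159 for chemokines, -1.862 for pro-inflammatory cytokines, -1.565 for interferon-stimulated genes and -0.971 for NF-kB members and feedback genes, which kept the call with an estimated correlation. They were -0.338 for anti-inflammatory regulators, -0.368 for immediate early genes, -0.289 for TLR4 signalling, -0.319 for the inflammasome, -0.382 for antigen presentation, -0.407 for mitochondrially encoded genes, -0.435 for LXR targets, -0.278 for ATF4 and unfolded protein response genes, -0.338 for p53 targets and -0.165 for sterol synthesis. They were 0.205 for cell cycle genes and 0.39 for MYC targets, and these 12 lists had adjusted p between 0.145 and 0.554 with an estimated correlation.

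For the 10 genes whose LPS response differed, 12 of 60 drawn reassignments of PBS and LPS within each genotype (of 200 possible) gave as many genes, the real one included, so chance cannot be excluded for that count. The reassignments treated all libraries of a genotype as exchangeable. They ignored the near-identical pairs and the shared deviations of control libraries of the same number. The highest other reassignment called 393 genes, which points to a structure of the samples. Within control cells the LPS count was 93 and the highest of the other splits 0, with 1 of 10 splits as large, too few for a share under 0.05. Within knockdown cells the real count was 0, so that 10 of 10 splits were as large whatever the data, which tests nothing. The highest other split there called 1431 genes and points to a structure of the samples. It set knockdown PBS replicates 1 and 3 and LPS replicate 3 against the rest, which kept on 1 side PBS replicate 3 and LPS replicate 3, libraries that differed by only 5.39 times the sampling variance. For knockdown against control 1 of 10 splits was as large in either treatment, too few for a share under 0.05, with 2545 genes in PBS and 3498 in LPS against a highest other of 0 in both.

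BRD3 was not called lower in the libraries labelled BRD3 knockdown. An exchange of genotype labels between 2 libraries needs a library out of place in each genotype, and 0 of the 12 libraries correlated better with the other genotype, which argues against it. A 2-fold fall hidden by the spread between libraries stays open: the 95% interval with near-identical pairs counted once reached a log2 fold change of -1.043 in LPS, and -1.119 in PBS when knockdown PBS replicate 1 was also left out. Lower BRD3 protein without a lower transcript was not tested, since no protein was measured in the data used here.

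The libraries labelled BRD3 knockdown had little LPS response among the 83 genes induced in control cells. PBS and LPS labels exchanged between knockdown libraries would place those genes high in a knockdown PBS library, but the highest such library lay at -0.089 on the log2 scale relative to control PBS. The spread brought by knockdown PBS replicate 1 does not hide a response of the control size, since the median without it was 0.204 against 1.88 in control cells. Low CD14, the LPS co-receptor, may contribute and stays open. Control replicate 3, with 14 and 5.79 CPM of CD14, still had a median LPS change of 2.088, but its PBS level lay above the highest knockdown level of 11.4. TLR4 held 5.9, 6.13 and 13.9 CPM in knockdown LPS, against 27.6, 28.5 and 14.3 in control LPS. In PBS it held 50.8, 7.39 and 14.2 CPM in knockdown libraries, against 32.6, 32.9 and 25.1 in control libraries. LY96, of the TLR4 signalling list, was called lower in LPS. It held 0.0381, 0.0393 and 0.182 CPM there, against 1.32, 1.38 and 0.382 in control LPS, near the floor. A part of TLR4 or LY96 was not tested. LPS that did not reach or act on the knockdown LPS cultures, and an effect of the knockdown itself, stay open. The labels stated no control hairpin, so an effect of introducing a hairpin cannot be told apart from one of the knockdown. None of the 83 genes passed. In 17 of them all knockdown LPS libraries lay above all knockdown PBS libraries, and in 3 below. The shares among the other tested genes were 5.2% and 5.6%. Near-identical libraries count as separate there, and genes are not independent. NF-kB members and feedback genes had small positive median LPS changes of 0.462, 0.406 and 0.254 by replicate number in knockdown cells, on the scale of log2(CPM + 1). That list was not called with an estimated correlation. Replicate numbers were not taken as pairs in knockdown cells, and knockdown LPS replicates 1 and 2 were near-identical. The values by number are therefore not independent replicates of a response.

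Knockdown PBS replicate 1 stood apart, with 324 CPM of GATA2, a haematopoietic transcription factor, against at most 34.5 in other libraries. It held 0 CPM of ZNF462, the level of the control libraries (0 to 0.0637 CPM), against 7.54 to 15.2 in the other knockdown libraries. RNA of T, B, erythroid or epithelial and fibroblast cells would bring most of their markers, but at most 18.8% of the markers of any of these lists were over 1 CPM and over 2 times the highest other library. Those were TRAC at 13.9, CD8A at 7.68 and GNLY at 1.65 CPM, while CD3D, CD3E and LCK were at 0. A control library under a knockdown label could not be excluded. Positions were taken over genes called for knockdown in LPS. These differed by at least 1 on the log2 scale there and, in the same direction, between the PBS reference libraries. With control PBS at 0 and the other knockdown PBS libraries at 1, the median position of knockdown PBS replicate 1 was 0.766. Control PBS replicate 3 had 0.335, with control PBS replicates 1 and 2 at 0. Knockdown PBS replicate 2 had 0.873, with knockdown PBS replicate 3 alone at 1. Gene sets and references thus differed between the 3 values. No biological explanation was tested.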

How the results depend on the processing

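The fits with near-identical pairs counted once, those that also leave out knockdown PBS replicate 1, and the blocked fits of control or knockdown cells alone were chosen only after the result was seen; all other alternatives were planned. No named gene and no list turned its direction past the threshold. Over named genes and alternatives 3251 results were the same, 546 no longer passed and 31 newly passed; over gene lists these numbers were 2515, 156 and 68. The cause of the changes below was not tested, except that stricter thresholds lower counts by construction.

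With near-identical pairs counted once, the counts were 4 for LPS in control cells, 281 for knockdown in PBS, 524 in LPS, 0 for the difference of LPS responses, 199 for the overlap of the knockdown calls, and 4 of 4 for LPS-induced genes lower with knockdown. When knockdown PBS replicate 1 was also left out, they were 1, 374, 983, 0, 325 and 1 of 1. With DESeq2 they were 273 for LPS in control cells, 19 for LPS in knockdown cells, 124 for the difference, 1 for the overlap of LPS calls, and 140 of 157 LPS-induced genes lower with knockdown (1 higher). Without a filter on low counts 174 genes changed with LPS in control cells and 55 differed in LPS response. With only the groups compared, 1018 genes changed with knockdown in PBS. At an adjusted p under 0.01 the counts were 43 for LPS in control cells, 872 and 1551 for knockdown in PBS and LPS, 2 for the difference and 614 for the overlap. Requiring at least 1 on the log2 scale left 1426 and 1941 for knockdown in PBS and LPS. With LPS-induced genes defined by at least 2 on the log2 scale, 35 of 38 were lower with knockdown, and defined in knockdown cells there were none, which gave no value.

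With the replicate number as a block, the difference of LPS responses had 16 genes, and control cells alone gave 1776 genes for LPS, or 1245 with near-identical pairs counted once. The block changed no other count by over 1.5 times: 68 for LPS in control cells, 0 in knockdown cells (also 0 in knockdown cells alone), 2577 and 3547 for knockdown in PBS and LPS. Leaving out each library in turn gave 47 to 77 genes for LPS in control cells, 0 to 535 for LPS in knockdown cells, 983 to 2818 for knockdown in PBS, 1949 to 3667 for knockdown in LPS, 2 to 54 for the difference, and 42 to 86 LPS-induced genes lower with knockdown. Where this left 2 libraries in a group, their spread was pooled with the other groups. Scaling by library size alone moved the median of all genes to -0.10 on the log2 scale for LPS in control cells, with 76 higher and 11 lower. Genes near 0 counts in a group, such as IL6 and IRG1, are limited by depth.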

Other observations

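The comparison in the first paragraph was planned before the data were examined; the values in the others were chosen only after they were seen.

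Genes known to respond to BET inhibitors went both ways. The list did not separate genes that such inhibitors raise from those they lower. Its counts, median and list test therefore cannot tell whether the changes resembled BET inhibition. Of 16 tested members, 2 rose and 2 fell in PBS and 3 rose and 3 fell in LPS in the libraries labelled BRD3 knockdown (0 and 0, and 1 and 0, with near-identical pairs counted once), with median log2 fold changes of -0.13 and -0.16 (adjusted p = 0.829 and 0.885 with an estimated correlation). BCL2 rose in both treatments, while CD180, a TLR4 homologue of B cells and monocytes, fell from 34.7 ± 10.7 to 3.53 ± 3.85 CPM in PBS (SD, n = 2 and 3) and from 19.8 ± 11.4 to 1.64 ± 0.00860 in LPS (n = 2 and 2; edgeR adjusted p = 0.00524 and 0.00226). IL7R, the IL-7 receptor, stood at 33.8 ± 11.4 CPM in control LPS and 3.91 ± 1.16 in knockdown LPS (adjusted p = 0.00125). The calls of BCL2, CD180 and IL7R were lost with near-identical pairs counted once (adjusted p = 0.0675 and 0.067 for CD180 and 0.0546 for IL7R). P53 targets went both ways in LPS, with 2 of 20 higher and 6 lower (1 and 2 with pairs counted once). ZMAT3 rose to 17.2 ± 0.711 CPM (log2 fold change 1.64 ± 0.18) and TP53I3 fell from 15.0 ± 3.36 to 4.06 ± 1.06 CPM (adjusted p = 0.000186 and 0.000377).

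Control replicate 3 lay towards the knockdown libraries. Across 15156 genes, which are not independent replicates, the difference of control PBS replicate 3 from replicates 1 and 2 correlated with the knockdown fold change in LPS at r = 0.507 (rho = 0.459), and that of control LPS replicate 3 with the knockdown fold change in PBS at r = 0.394 (rho = 0.306). Each of these pairs shares no library but is not independent, since control PBS and control LPS libraries of the same number deviated together. Part of each correlation may come from this.

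CAP1, an actin-binding protein gene, held 10200 to 15900 CPM in every library, and its neighbours on chromosome 1, PPT1 and SMAP2, held 4220 to 5760 and 1740 to 3430 CPM.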
